A study of Nematostella vectensis with 33 samples.

How the data were processed

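Messenger RNA was sequenced from whole polyps and from microinjected embryos of the sea anemone Nematostella vectensis, in 33 libraries that formed 16 groups. Per the labels, polyps were left untreated or received 1 of 4 cyclic dinucleotides at 500 µM for 24 h, and embryos received 2'3'-cGAMP at 100 µM for 4 h or none. RNA from polyps was extracted on columns and made into libraries with a WaferGen kit, whereas embryo RNA was extracted in Trizol and made into libraries with KAPA kits, so polyp and embryo values were never placed in the same fit. The embryo libraries formed 2 experiments, each with its own table: one with short hairpin RNAs (shRNAs) against GFP or STING, the other with shRNAs against GFP, NF-kB or STAT.

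The authors deposited 3 tables of signal values per gene, which the labels call normalized counts. The submitters' notes name FastQC 0.11.9, kallisto 0.46.1 (a pseudoaligner) and DESeq2, without a role or an order, and the transcriptome build was not stated. The values were not whole and never negative. In the polyp table, 82.1 to 83.5% of the positive values below 2000 steps per library were whole multiples of 1 step (tolerance 0.0001 of a step). In the embryo tables at most 0.1% were. Whole reads could therefore not be recovered for part of the polyp values and nearly all embryo values, and no test made for raw counts was run. The depth per library was estimated by dividing the deposited total by the value of 1 read, which is approximate in embryos, where low values lay close to whole reads less often. Columns did not sum to a common total, and the deposited scaling was kept in the main tests.

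Genes with a value of at least 10 in at least 2 libraries of a table were tested: 18511 of 21260 in polyps, 20879 of 22407 in the STING experiment and 20058 of 22111 in the NF-kB and STAT experiment. Values were moved to log2 with a pseudocount of 1 and fitted with limma 3.58.1 in R 4.3.3, as a mean per group with all groups of the table in 1 fit, moderated variances and a trend on mean expression. P-values were two-sided and adjusted by Benjamini-Hochberg over the tested genes within each of 18 comparisons, and a gene was called at an adjusted p below 0.05. Effects of shRNAs were taken as the mean of both hairpins against the same gene, and the difference in response was the interaction between shRNA and treatment. The p-values measure only the spread between these samples, since the labels do not say whether libraries came from separate animals or cultures. Without any change, a share of about 0.05 of the tested genes would have an unadjusted p below 0.05 on average. Where more genes than that share lay below 0.05, a count of 0 called genes does not show the absence of a difference.

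Lists of genes were tested with camera (preset correlation between genes of 0.01, and an estimated correlation as an alternative) and with fry, both in limma. Camera compares a list with the other genes, whereas fry tests whether the list's genes move on balance in 1 direction. The mean of a list per library was compared between groups with a pooled spread, and its 95% interval is given. Comparisons, tests, filters, the rule for named genes and most alternatives were chosen before the data were examined. A further 24 lists of pathways and cell types chosen at that time, among them cyclic dinucleotide sensing, NF-kB, STAT, antiviral genes and cell-type markers, matched 0 genes, because the reference table (assembly jaNemVect1.1) gives placeholder symbols with the prefix LOC and the tables give NCBI Gene identifiers. The lists built from the data themselves were tested in libraries other than those they came from, except where stated.

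Identifiers were matched to the reference for 76.4% of the polyp genes, 74.5% of the genes in the STING experiment and 74.8% in the NF-kB and STAT experiment. No genomic positions are given, since the build behind the values is not stated. The rule for genes without usable names took at most 2 genes that rose and 2 that fell per comparison, with the largest changes among those called, a mean of at least 50 over the compared libraries and no overlap between the compared groups. Genes of a count of 5 or fewer outside that rule were named after their values were seen. Where a gene named for one comparison is also quoted for another, that choice was made after its values were seen.

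Alternatives covered the pseudocount (0.5 and 5), the filter (none, and a mean of at least 50), scaling by TMM factors (trimming 30% of ratios and 5% of intensities) or by quantiles, robust variance moderation, array quality weights, a fit with the compared groups alone, the replicate number as a block, an adjusted p below 0.01, an absolute log2 change of at least 1, each hairpin on its own, and each library left out in turn. Equal library totals, the STING experiment without the 2 libraries with most genes at 0, and the STING experiment with the place in the sample order as a block were added after the data were seen. The gene calls of the 18 comparisons were tested on simulated data with 200 changed genes, drawn among genes with a mean of at least 50. No simulated library was given an excess of genes at 0, and recovery among genes with lower means was not measured. The list tests, overlaps and splits were not tested on simulated data. Tables were read and figures drawn with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.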

Results

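Transcript levels were measured in whole polyps given cyclic dinucleotides, the small second messengers that bind the receptor STING, and in embryos injected with shRNAs and given 2'3'-cGAMP. The polyp table held 5 groups of 2 libraries. These were polyps given 3'3'-cGAMP, 2'3'-cGAMP, c-di-GMP or c-di-AMP, and untreated polyps. The STING experiment held 6 groups of 2 libraries, with a GFP shRNA as control and 2 STING shRNAs, each untreated and with 2'3'-cGAMP. The NF-kB and STAT experiment held 3 GFP shRNA libraries and 2 libraries for each of 2 NF-kB and 2 STAT shRNAs, all with 2'3'-cGAMP and with no untreated embryos. The genes targeted by the shRNAs could not be paired with identifiers, so the depletion of their transcripts was not analysed here.

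Estimated depth ran from 9.4 to 17.4 M (mega) reads per library in polyps, from 16.7 to 30.6 M in the STING experiment and from 14.4 to 25.6 M in the NF-kB and STAT experiment. Deposited totals in polyps ran from 9.56 to 10.55 M except in the 2'3'-cGAMP libraries, which had 22.34 and 22.36 M. In those libraries 11.3% and 9.8% of genes were listed at 0, against 3.8 to 5.8% in the other polyp libraries. In the STING experiment the share of genes at 0 was 21.6% in GFP shRNA untreated library 1 and 14.4% in GFP shRNA 2'3'-cGAMP library 4, against 4.0 to 11.3% in the other libraries. Replicates of a group correlated across genes with a Pearson's r of 0.941 to 0.962 in polyps, 0.871 to 0.958 in the STING experiment and 0.916 to 0.967 in the NF-kB and STAT experiment, where genes are not independent replicates.

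**Figure D1:**
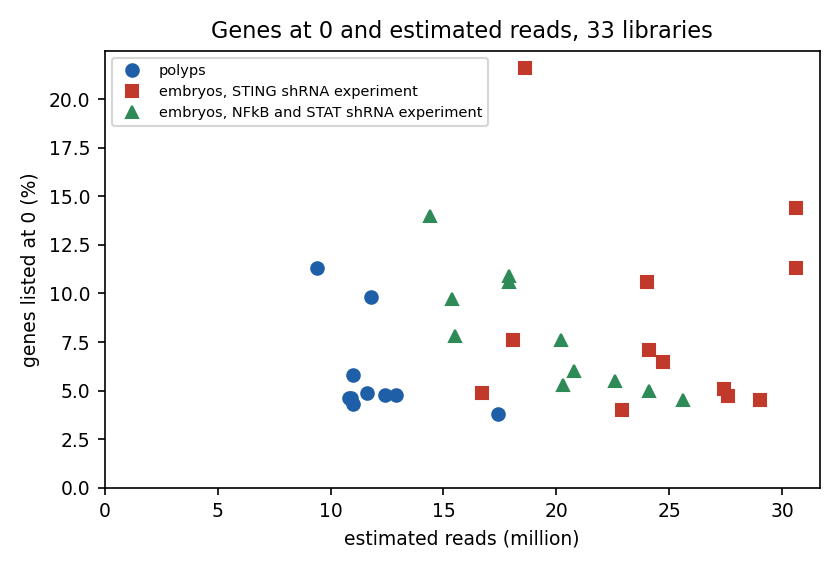
Each point is 1 of the 33 libraries, with estimated reads (M) on the horizontal axis and the share of genes listed at 0 (%) on the vertical axis, and the markers show the 3 tables. The library with the most genes at 0 (21.6%) had an estimated 18.6 M reads, and a library with fewer reads (16.7 M) had 4.9% of genes at 0.

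Polyps given 2'3'-cGAMP differed from untreated polyps in more than 50% of the tested genes. LOC5514999 rose from 2.62 ± 1.30 normalised counts (SD, n = 2) in untreated polyps to 6380 ± 658 (n = 2), a log2 change of 10.83, and NCBI Gene 116615652 rose from 4.37 ± 2.58 to 7903 ± 1595, a log2 change of 10.60. NCBI Gene 116617477 fell from 1567 ± 254 to 23.1 ± 2.26, a log2 change of -6.02, and NCBI Gene 116604992 was listed at 0 in both 2'3'-cGAMP libraries against 143 ± 25.2 in untreated polyps. Limma called 10828 of 18511 genes (58.5%), 5271 higher and 5557 lower, whereas 1089 of the higher and 724 of the lower genes changed by at least 3 on the log2 scale. The adjusted p was 1.2e-07 for LOC5514999, 2.9e-08 for Gene 116615652, 2.16e-07 for Gene 116617477 and 0.000225 for Gene 116604992. The balance of directions rests on the deposited scaling. When library totals were made equal, the median of all genes moved to -1.21 on the log2 scale and 15.8% of 13421 called genes were higher. No named gene changed direction. Low values of Gene 116604992 were not particular to 2'3'-cGAMP. It stood at 3.05 ± 2.10 with c-di-AMP and 4.04 ± 2.02 with c-di-GMP, although not called there, and at 12.3 and 200.9 in the 3'3'-cGAMP libraries.

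The other compounds, at the same dose and time, gave smaller responses. With c-di-AMP, LOC5517508 rose from 39.0 ± 2.54 to 332 ± 55.8 normalised counts (log2 change 3.05, adjusted p = 0.000294 by limma, n = 2 each) and LOC5516210 from 301 ± 67.8 to 1692 ± 12.5 (log2 change 2.50, adjusted p = 0.000294). Both genes were higher in each c-di-AMP library than in any untreated library. With c-di-AMP 143 genes were called higher and 3 lower. With 3'3'-cGAMP 10 genes were called, all higher, among them LOC5516250, from 926 ± 69.5 to 3090 ± 244 (log2 change 1.74, adjusted p = 0.000756), and LOC5517508 at 139 ± 4.42 (log2 change 1.81, adjusted p = 0.0212). With c-di-GMP limma called 0 genes, 1877 had an unadjusted p below 0.05, and LOC5517508 stood at 42.6 ± 13.3. Those 1877 genes are more than a share of 0.05 of the tested genes, so 0 calls do not show the absence of a response. The median gene's 95% interval reached 0.625 to either side on the log2 scale.

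All 143 genes higher with c-di-AMP were also higher with 2'3'-cGAMP, where 40.7 would be shared by chance, but both comparisons used the same untreated libraries. Against c-di-GMP instead, which shares no library with 2'3'-cGAMP against untreated, 130 genes were higher with c-di-AMP and all 130 were higher with 2'3'-cGAMP (37 by chance). The mean of the 143 genes in 2'3'-cGAMP polyps exceeded that in untreated polyps by 5.85 on the log2 scale (95% interval 5.57 to 6.13), against 1.43 (1.15 to 1.72) with c-di-AMP, by which the list was chosen. The 3 genes lower with c-di-AMP, 2 of them named after their values were seen, were NCBI Gene 5502658 (log2 change -1.41, adjusted p = 0.0206 by limma), NCBI Gene 5501765 (-1.92, 0.0449) and LOC116618267 (adjusted p = 0.015), which was listed at 0 in both c-di-AMP libraries against 43.7 ± 18.5 untreated. Without any 1 of the 4 c-di-AMP and untreated libraries none of these 3 genes was called, with adjusted p from 0.121 to 0.159, from 0.202 to 0.251 and from 0.0878 to 0.142. The count of 146 for c-di-AMP fell to 67 without untreated library 1, to 64 without untreated library 2 and to 35 without c-di-AMP library 1. The count of 10 for 3'3'-cGAMP fell to 6, 5 and 3 without untreated library 1, untreated library 2 and 3'3'-cGAMP library 2, and without each of the 4 libraries LOC5517508 was no longer called there (adjusted p 0.0639 to 0.115). A fit with the compared groups alone called 0 genes for 3'3'-cGAMP (limma, 606 at an unadjusted p below 0.05). For c-di-GMP, 3 genes were called without untreated library 1, untreated library 2 or c-di-GMP library 1, and the compared groups alone gave 115.

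Compared directly, 2'3'-cGAMP differed from each of the other compounds, including its isomer 3'3'-cGAMP, which differs in 1 phosphodiester linkage. LOC5514999 stood at 6380 ± 658 normalised counts with 2'3'-cGAMP, 2.42 ± 1.84 with 3'3'-cGAMP, 2.93 ± 0.291 with c-di-AMP and 1.80 ± 1.32 with c-di-GMP (n = 2 each). Limma called 10746 genes between 2'3'-cGAMP and 3'3'-cGAMP (5287 higher with 2'3'-cGAMP), 10361 against c-di-AMP (5143 higher) and 10365 against c-di-GMP (5108 higher). With equal totals 15.4%, 15% and 15.5% of the called genes were higher. Between c-di-AMP and c-di-GMP, 130 genes were higher with c-di-AMP, among them LOC5517508 (log2 difference 2.96, adjusted p = 0.000183) and NCBI Gene 5500431 (2.55, 0.0103). 1 gene was called lower, NCBI Gene 116616108, listed at 0 in both c-di-AMP libraries. Between 3'3'-cGAMP and c-di-GMP, 13 genes were higher with 3'3'-cGAMP, such as LOC5518711 (log2 difference 1.95, adjusted p = 0.0341) and LOC116618106 (1.74, 0.0304). The other called gene, NCBI Gene 116618505, was listed at 0 with 3'3'-cGAMP. Between 3'3'-cGAMP and c-di-AMP, 1 gene was called, NCBI Gene 5519757, with 348 ± 61 normalised counts against 929 ± 111 (log2 difference -1.42, 95% interval -1.75 to -1.09, adjusted p = 0.0354 by limma).

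These 3 smaller counts moved when single libraries were left out. A group of 2 then keeps 1 library, so part of a fall in calls can follow from that alone. Without 3'3'-cGAMP library 1, which at an estimated 17.4 M reads was the deepest in polyps, 262 genes were called between 3'3'-cGAMP and c-di-AMP and 128 between 3'3'-cGAMP and c-di-GMP. Without c-di-AMP library 1, c-di-AMP library 2 or 3'3'-cGAMP library 2 the former count was 3, 5 or 0, and without c-di-GMP library 2 or 3'3'-cGAMP library 2 the latter was 1 or 5. The count of 131 between c-di-AMP and c-di-GMP fell to 53 without c-di-AMP library 1 and to 51 without c-di-GMP library 2. Gene 5519757 was not called without c-di-AMP library 1 or 3'3'-cGAMP library 2 (adjusted p 0.187 to 0.244), Gene 5500431 not without c-di-AMP library 1 or c-di-GMP library 1 (0.0729 to 0.18), and Gene 116616108 not without any 1 of its 4 libraries (0.111 to 0.226). LOC5518711 (0.1 to 0.248) and LOC116618106 (0.139 to 0.198) lost the call without c-di-GMP library 1, c-di-GMP library 2 or 3'3'-cGAMP library 2, and Gene 116618505 (0.139 to 0.477) without either of the last 2.

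In embryos with the GFP shRNA, 2'3'-cGAMP raised many genes. LOC116612243 rose from 0.448 ± 0.634 to 1393 ± 101 normalised counts (log2 change 9.98, adjusted p = 2.2e-06 by limma, n = 2 each) and NCBI Gene 5519817 from 7.46 ± 10.6 to 2264 ± 513 (log2 change 9.13, adjusted p = 0.000428). NCBI Gene 116618930 fell from 260 ± 126 to 11.8 ± 16.6 (log2 change -5.63, adjusted p = 0.0193) and LOC5514457 from 110 ± 44.8 to 5.42 ± 7.67 (-4.94, 0.018). Limma called 1211 of 20879 genes, 943 higher and 268 lower (77.9% higher, against 57.2% of 1274 with equal totals). The count was 735 without GFP shRNA untreated library 1, 2781 without GFP shRNA untreated library 2 and 743 without GFP shRNA 2'3'-cGAMP library 4. It was 565 without untreated library 1 and 2'3'-cGAMP library 4, the pair with most genes at 0, 427 with the compared groups alone and 614 with array quality weights. Gene 116618930 was not called without untreated library 1 or 2'3'-cGAMP library 4 (adjusted p 0.0547 to 0.117), and LOC5514457 not without the latter (0.0747).

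The genes that responded in embryos largely responded in polyps. Of 927 genes higher with 2'3'-cGAMP in GFP shRNA embryos and tested in polyps, 882 (95.1%) were higher in 2'3'-cGAMP polyps, where 269 would be by chance. Of 258 lower genes 210 were lower (78.5 by chance). The polyp directions and means in this paragraph use the deposited scaling, and equal library totals were not tried for these lists. The polyp genes higher with 2'3'-cGAMP moved up in GFP shRNA embryos (camera adjusted p = 2.05e-32 over 8 tests) and the polyp genes lower moved down (2.1e-20). With an estimated correlation the adjusted p was 0.000434 and 0.000191. As a list chosen after the data were seen, the 927 embryo genes had a mean in polyps that exceeded the untreated one by 3.82 on the log2 scale with 2'3'-cGAMP (95% interval 3.66 to 3.99), by 0.46 with c-di-AMP (0.30 to 0.63) and by 0.22 with 3'3'-cGAMP (0.052 to 0.38). With c-di-GMP the difference was -0.023 (-0.19 to 0.14). The mean with 3'3'-cGAMP lay below that with c-di-AMP by a log2 difference of -0.25 (-0.41 to -0.08).

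**Figure D2:**
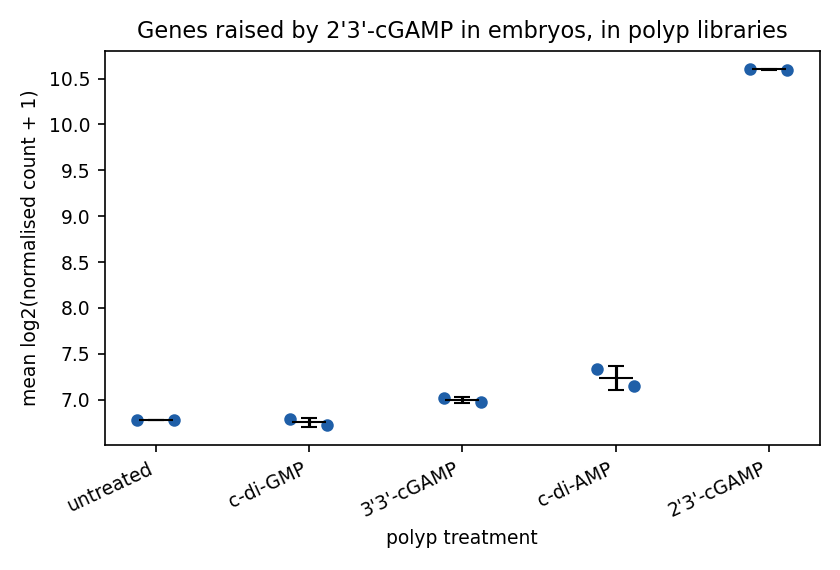
Points are the polyp libraries, with the mean log2(normalised count + 1) of the 927 genes called higher with 2'3'-cGAMP in GFP shRNA embryos on the vertical axis and treatment on the horizontal axis, and lines are the group mean and SD. The 2'3'-cGAMP group stood at 10.60, c-di-AMP at 7.24, 3'3'-cGAMP at 6.99, c-di-GMP at 6.75 and untreated at 6.78.

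Embryos with STING shRNAs were used to ask whether STING is required for the response, and they also responded to 2'3'-cGAMP. NCBI Gene 5519817 rose from 5.48 ± 7.63 to 1613 ± 485 normalised counts (log2 change 8.89, adjusted p = 2.24e-05 by limma, n = 4 each) and NCBI Gene 116615652 from 25.8 ± 24.1 to 3498 ± 514 (8.07, 2.25e-05). NCBI Gene 116619077 fell from 119 ± 31 to 14.0 ± 5.61 (-3.04, 0.00275) and LOC5514948 from 90.2 ± 22.4 to 16.5 ± 13.1 (-3.15, 0.0415). Limma called 2272 genes, 1483 higher and 789 lower, and 880 of the 943 genes higher in GFP shRNA embryos were higher here (67 by chance). Larger counts than with the GFP shRNA came from 4 libraries against 4, and a count does not compare the responses. With equal totals 1070 of 2981 called genes were higher. The count fell to 1417 without STING shRNA 1 2'3'-cGAMP library 1, to 1269 and 1283 without STING shRNA 2 untreated libraries 1 and 2, and to 1367 and 1278 without STING shRNA 2 2'3'-cGAMP libraries 1 and 2. LOC5514948 was called in none of 7 of the 8 fits with 1 library left out (adjusted p 0.0711 to 0.138), the exception being the fit without STING shRNA 1 2'3'-cGAMP library 2.

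The test of the difference in response called no gene. LOC5514999 rose by 6.03 on the log2 scale with the GFP shRNA and by 5.07 with the STING shRNAs, a difference of -0.96 (95% interval -2.23 to 0.31, adjusted p = 1 by limma). Limma called 0 of 20879 genes, with 311 at an unadjusted p below 0.05 and a median interval of 1.41 to either side. Those 311 genes are fewer than a share of 0.05 of the tested genes, the share without any change. In simulated data for this comparison limma recovered 0% of 2-fold, 17.9% of 4-fold and 47% of 8-fold differences, among genes with a mean of at least 50. The polyp genes higher with 2'3'-cGAMP had a camera adjusted p of 0.053 for this difference (0.246 with an estimated correlation). That of the higher genes was 0.0198 with polyp genes of an absolute log2 change of at least 1, 0.0272 with a mean of at least 50, 0.0428 with TMM factors and 0.043 (over 4 tests) with the sample order as a block. The lower genes had an adjusted p of 0.112 (0.155 with an estimated correlation, 0.0402 with a mean of at least 50), with a median of 0.025 and a mean of -0.018. Without GFP shRNA untreated library 2, when untreated library 1 stood alone, 660 genes were called, 75.3% of them at 0 in that library. Leaving out 1 library moved the list tests too: the adjusted p of the higher genes was 0.00606 without GFP shRNA 2'3'-cGAMP library 4 and 0.0443 without STING shRNA 1 untreated library 1. For the lower genes it was 0.000757 and 0.0399 without those 2 libraries and 0.00691 without GFP shRNA untreated library 2, and the direction turned without GFP shRNA untreated library 1 (0.279) or 2'3'-cGAMP library 5 (0.745).

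Within a treatment, limma called at most 1 gene between STING and GFP shRNA embryos when all libraries were used. In simulated data it recovered 10.4% of 2-fold and 58.2% of 4-fold differences in 2'3'-cGAMP, and 11.9% and 47.8% in untreated embryos. In 2'3'-cGAMP, LOC5517508 differed by -0.21 on the log2 scale (95% interval -1.05 to 0.63), and limma called 0 genes with 1616 at an unadjusted p below 0.05. Those 1616 genes are more than a share of 0.05 of the tested genes. In untreated embryos LOC116612243, named after its values were seen, stood at 27.5 ± 13.5 normalised counts with the STING shRNAs (n = 4) and 0.448 ± 0.634 with the GFP shRNA (n = 2), a log2 difference of 4.24 (adjusted p = 0.0261 by limma). There 1374 genes had an unadjusted p below 0.05. That gene was not called without GFP shRNA untreated library 1 or any 1 of the 4 STING shRNA untreated libraries (adjusted p 0.0701 to 0.176), and those fits called 0 genes. Without GFP shRNA untreated library 2, 1506 genes were called in untreated embryos, 62.4% of them at 0 in the remaining control library. Without GFP shRNA 2'3'-cGAMP library 5, 70 genes were called in 2'3'-cGAMP, 65.7% of them at 0 in library 4.

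The genes higher with c-di-AMP in polyps, a list chosen after the data were seen, were strongly raised by 2'3'-cGAMP in embryos. Their mean rose by 3.94 on the log2 scale with the GFP shRNA (95% interval 3.56 to 4.32) and by 3.43 with the STING shRNAs (3.16 to 3.69), and 124 of the 143 genes were called higher in GFP shRNA embryos (7.42 by chance). In 2'3'-cGAMP the means with STING and GFP shRNAs differed by 0.001 (-0.33 to 0.33) and in untreated embryos by 0.51 (0.19 to 0.84), so the responses differed by -0.512 (-0.974 to -0.049). By hairpin the responses differed by -0.339 (-0.873 to 0.195) for STING shRNA 1 and -0.684 (-1.218 to -0.15) for STING shRNA 2. The pooled interval included 0 in 8 of 12 fits with 1 library left out. Without GFP shRNA untreated library 1 the difference in untreated embryos was 0.37 (-0.04 to 0.78).

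**Figure D3:**
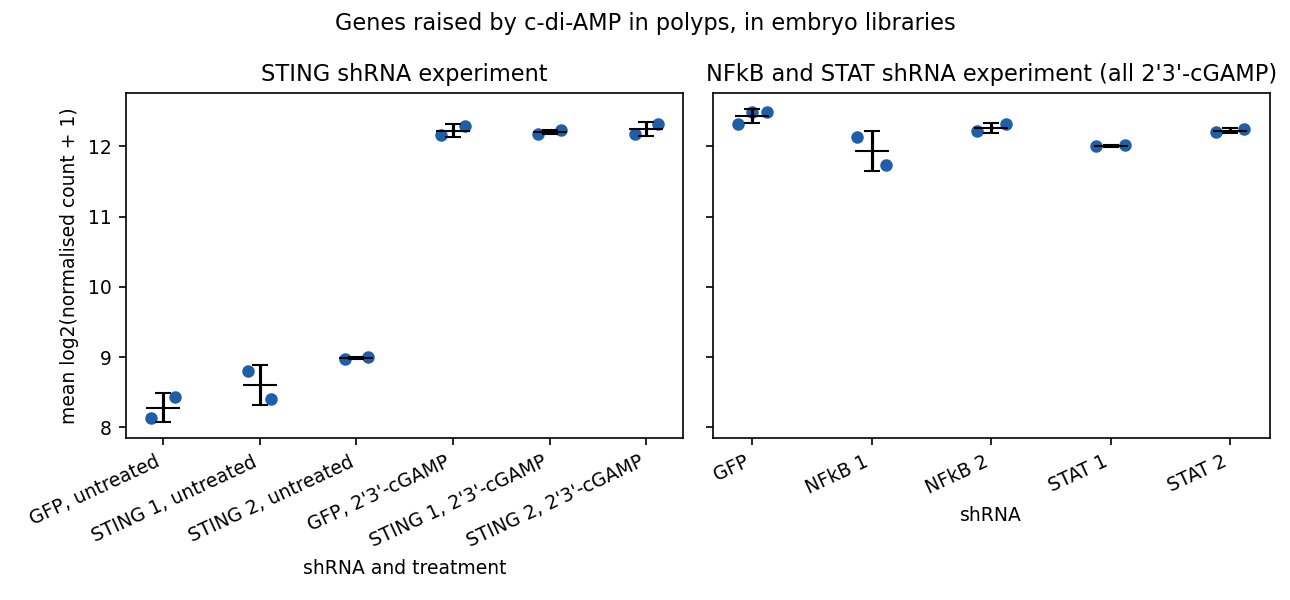
Points are embryo libraries, with the mean log2(normalised count + 1) of the 143 genes called higher with c-di-AMP in polyps on the vertical axis, by shRNA and treatment; lines are the group mean and SD. In the STING experiment untreated groups stood at 8.28 to 8.99 and 2'3'-cGAMP groups at 12.20 to 12.25.

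NF-kB shRNAs, used to ask whether this transcription factor is required, lowered some of the genes that 2'3'-cGAMP raises. LOC5514999, the gene with the largest rise in polyps, stood at 627 ± 488 normalised counts with the NF-kB shRNAs (n = 4) and 6417 ± 1603 with the GFP shRNA (n = 3). The log2 difference was -3.65 (adjusted p = 0.000651 by limma), and -3.65 to -3.66 for each hairpin. The gene lay below the 3 controls in all 4 libraries, at 474.5 and 523.7 with hairpin 1 but at 186.8 and 1325 with hairpin 2. It was also below the controls in all 4 STAT shRNA libraries (1269 to 3102 against at least 4874), with a difference of -1.44 (95% interval -2.41 to -0.46, adjusted p = 0.829). Between NF-kB and STAT shRNAs it differed by -2.22 (adjusted p = 0.0117). LOC116620691 stood at 13.2 ± 12.5 against 101 ± 25.9 (-3.68, 0.00352), NCBI Gene 5510255 at 10890 ± 2790 against 1648 ± 545 (2.75, 0.00136) and LOC116603002 at 144 ± 74.2 against 25.9 ± 15.9 (2.49, 0.0297). Limma called 555 of 20058 genes, 241 higher and 314 lower. Of the 943 genes higher with 2'3'-cGAMP in GFP shRNA embryos, 111 were lower with the NF-kB shRNAs (14.9 by chance) and 52 were higher (11.5 by chance). Of 308 genes lower with the NF-kB shRNAs 252 were higher in 2'3'-cGAMP polyps (90.8 by chance), and of 239 genes higher 145 were (70.4 by chance), with the deposited scaling of the polyp table. As a list the 943 genes passed camera with the preset correlation but neither other test. Their mean differed by -0.136 (95% interval -0.405 to 0.134), with an adjusted p over 72 tests of 0.0224 by camera, 0.69 with an estimated correlation and 0.425 by fry.

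Relative to the other genes, the polyp genes higher with 2'3'-cGAMP ranked lower with the NF-kB shRNAs (camera adjusted p = 0.0285) and the polyp genes lower ranked higher (0.00925), calls lost with an estimated correlation (adjusted p = 0.385 and 0.246). The list means themselves differed from those with the GFP shRNA by -0.15 on the log2 scale (95% interval -0.30 to 0.002) and by 0 (-0.144 to 0.145). For the lower genes the hairpins went opposite ways (0.135 and -0.134), with 0.269 between them (0.08 to 0.458). Both camera calls were also lost without GFP shRNA library 2 (0.179 and 0.122) or NF-kB shRNA 1 library 2 (0.491 and 0.431). The count of 555 fell to 222 without NF-kB shRNA 2 library 1, in which 14% of genes were at 0, and to 188 without GFP shRNA library 2. With each hairpin in the same direction 154 genes were called, and array quality weights called 1927. Those weights were 5.25 for GFP shRNA library 2 but 1.17 and 0.43 for GFP shRNA libraries 1 and 3, so the 1927 calls lean on 1 control library. Between the hairpins limma called 0 genes, with 2329 at an unadjusted p below 0.05. Those 2329 genes are more than a share of 0.05 of the tested genes, so 0 calls do not show that the hairpins acted alike. LOC116603002 was not called without NF-kB shRNA 1 library 1, NF-kB shRNA 2 library 1, or GFP shRNA library 2 or 3 (adjusted p 0.102 to 0.138), nor with either hairpin alone, and LOC116620691 was not called with hairpin 1 alone.

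With STAT shRNAs 1 gene was called, and it was lower. LOC5514869 stood at 6580 ± 1539 normalised counts (n = 4) against 24080 ± 3584 with the GFP shRNA (n = 3), a log2 difference of -1.89 (95% interval -2.27 to -1.51, adjusted p = 0.000774 by limma), and it fell with hairpin 1 (-1.61, 0.0474) and with hairpin 2 (-2.17, 0.00131). The same gene rose by 5.65 in 2'3'-cGAMP polyps and by 3.24 in GFP shRNA embryos given 2'3'-cGAMP (adjusted p = 0.000842), and its difference with the NF-kB shRNAs was -0.30 (-0.68 to 0.09). Whether LOC5514869 is itself the transcript targeted by the STAT shRNAs could not be told, since no identifier could be paired with STAT. Limma called no other gene, with 1080 at an unadjusted p below 0.05. The count was 4 without GFP shRNA library 1, 2 without STAT shRNA 1 library 1 and 18 without STAT shRNA 1 library 2, and array quality weights called 54. The 54 calls lean on GFP shRNA library 2, which had a weight of 5.25 against 1.17 and 0.43 for GFP shRNA libraries 1 and 3. Relative to the other genes, the polyp genes higher with 2'3'-cGAMP ranked lower with the STAT shRNAs and the polyp genes lower ranked higher (camera adjusted p = 1.55e-07 for both). Both calls were lost with an estimated correlation (adjusted p = 0.138 and 0.0955). The list means differed by -0.125 (95% interval -0.277 to 0.027) and 0.105 (-0.039 to 0.25).

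**Figure D4:**
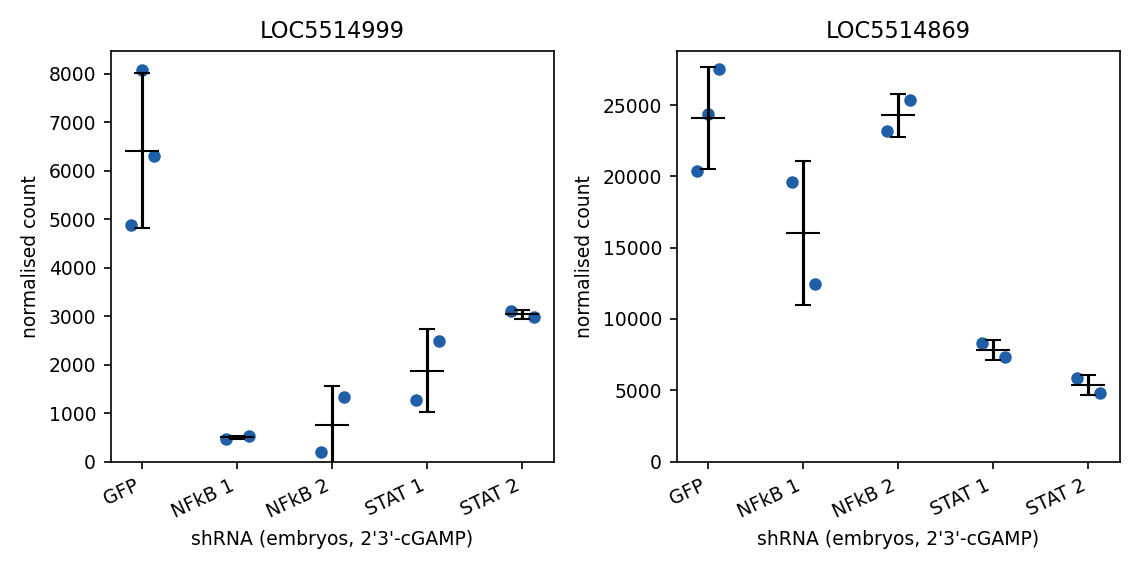
Points are embryo libraries given 2'3'-cGAMP, with normalised counts of LOC5514999 and LOC5514869 on the vertical axes and the shRNA on the horizontal axes; lines are the group mean and SD. LOC5514999 averaged 6417 with the GFP shRNA, 627 with NF-kB shRNAs, and 1875 and 3039 with STAT shRNAs 1 and 2. LOC5514869 averaged 24080 with the GFP shRNA and 6580 with STAT shRNAs.

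NF-kB and STAT shRNA embryos also differed from each other. LOC5512948 stood at 4786 ± 2015 normalised counts with the NF-kB shRNAs and 660 ± 498 with the STAT shRNAs (log2 difference 3.08, adjusted p = 0.00312 by limma, n = 4 each) and NCBI Gene 5510255 at 10890 ± 2790 against 2051 ± 962 (2.56, 0.00147). LOC116615369 stood at 59.6 ± 41.6 against 405 ± 98 (-3.23, 0.00381) and LOC5508611 at 17.6 ± 12.6 against 100.3 ± 56.5 (-3.08, 0.0371). Limma called 436 genes, 185 higher and 251 lower with the NF-kB shRNAs. The count was 262 without NF-kB shRNA 1 library 1, 191 without NF-kB shRNA 2 library 1, 290 without STAT shRNA 1 library 1, and 244 and 184 without STAT shRNA 2 libraries 1 and 2. LOC5508611 was not called without either NF-kB shRNA 1 library or any 1 of the 4 STAT shRNA libraries (adjusted p 0.0743 to 0.17), and LOC5512948 was not called with robust variance moderation.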

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

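The tests of the interval of the list mean and of the STING transcript were chosen after the result was seen, and the test with array quality weights was chosen before. The 143 genes higher with c-di-AMP in polyps rose by 3.94 on the log2 scale with 2'3'-cGAMP in GFP shRNA embryos and by 3.43 in STING shRNA embryos, and the difference in response between these groups drew attention because its interval excluded 0: -0.512 (95% interval -0.97 to -0.049). By hairpin it was -0.339 (-0.873 to 0.195) for STING shRNA 1 and -0.684 (-1.218 to -0.15) for STING shRNA 2, with 0.345 between them (-0.189 to 0.879). The adjusted p of the list was 0.0485 by camera with an estimated correlation and 0.0632 by fry, over 72 tests. The difference came from untreated embryos, in which the list mean was 0.51 higher with the STING shRNAs (0.19 to 0.84), while with 2'3'-cGAMP it differed by 0.001. The interval of the pooled difference in response included 0 in 8 of 12 fits with 1 library left out: without GFP shRNA untreated library 1 (-0.37), either GFP shRNA 2'3'-cGAMP library (-0.58 and -0.44 without libraries 4 and 5), either STING shRNA 1 2'3'-cGAMP library (-0.50 and -0.52), either STING shRNA 2 untreated library (-0.52 and -0.51) or STING shRNA 2 2'3'-cGAMP library 1 (-0.48). Without GFP shRNA untreated library 1, which had the most genes at 0, the difference in untreated embryos was 0.37 (-0.04 to 0.78).

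No gene was called for the difference in response between STING and GFP shRNA embryos (0 by limma, 311 at an unadjusted p below 0.05). Too few libraries is argued against for a loss of most of the response of the list as a whole. The lower bound of its difference, -0.974, lay above -1.97, the loss of 50% of the GFP shRNA response on the log2 scale. A loss of that size would be larger than 50% when counted in fold. Smaller losses stay open, and single genes were far less certain. Libraries with many genes at 0 stay open as a cause. Array quality weights also called 0 genes (152 at an unadjusted p below 0.05), but both libraries of a group of 2 got the same weight (0.411 for GFP shRNA untreated libraries 1 and 2). In simulated data without weights only 17.9% of 4-fold differences were recovered, so few calls were no sign against this cause. Hairpins that left the STING transcript at its level and a response that needs little STING cannot be told apart, since 0 identifiers could be paired with STING. Each of these may account for the result.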

How the results depend on the processing

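The tests with equal library totals, without the 2 libraries with most genes at 0, with the place in the sample order as a block, and of STING against GFP shRNAs over both treatments were chosen after the data were seen. The 4 comparisons of 2'3'-cGAMP with another polyp group stayed within 1.5 times their counts in all 13 alternatives each and without each library (8024 to 13421 genes against untreated). The balance of directions did not hold. With equal totals 15.8% of the called genes were higher than in untreated polyps (median log2 change -1.21), 15.4% than with 3'3'-cGAMP, 15% than with c-di-AMP and 15.5% than with c-di-GMP. With equal totals 57.2% of the genes called in the GFP shRNA response and 35.9% in the STING shRNA response were higher, and 55.1% of the latter with quantile scaling. These shifts follow from the construction of the alternatives, and which scaling is right was not tested. For 48 pairs of a named gene and a comparison, 772 of 883 alternative values kept their call, 111 lost it and 0 reversed. For other changes the cause was not tested, except that a stricter threshold cannot call more genes by construction. A hairpin on its own compares fewer libraries, and fewer calls can follow from that but are not forced. A fit with 1 library left out also holds fewer libraries, and fewer calls can follow from that alone.

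With an adjusted p below 0.01, counts were 1 for 3'3'-cGAMP and 56 for c-di-AMP against untreated, 0 for 3'3'-cGAMP against c-di-AMP, 1 for 3'3'-cGAMP against c-di-GMP, and 74 for c-di-AMP against c-di-GMP. They were 616 for the GFP shRNA and 1201 for the STING shRNA response, 0 for STING against GFP shRNAs untreated, 212 for NF-kB against GFP and 167 for NF-kB against STAT shRNAs. With the compared groups alone they were 0 for 3'3'-cGAMP and 115 for c-di-GMP against untreated, 0 for 3'3'-cGAMP against c-di-AMP, 1 for 3'3'-cGAMP against c-di-GMP, 427 for the GFP shRNA response and 0 for STING against GFP shRNAs untreated. Array quality weights gave 221 for c-di-AMP against untreated, 614 for the GFP shRNA response, 0 for STING against GFP shRNAs untreated, 1927 for NF-kB and 54 for STAT against GFP shRNAs. The last 2 counts lean on GFP shRNA library 2, with a weight of 5.25 against 1.17 and 0.43 for the other controls. For 3'3'-cGAMP against c-di-AMP, no filter gave 2, robust moderation 4 and equal totals 3. STING against GFP shRNAs untreated also gave 0 with a pseudocount of 5, with quantile scaling and without the 2 libraries with most genes at 0, which gave 565 for the GFP shRNA response. Over both treatments, STING against GFP shRNAs gave 0 by limma, with 3395 at an unadjusted p below 0.05. Those 3395 genes are more than a share of 0.05 of the tested genes, so 0 calls do not show the absence of a difference. An absolute log2 change of at least 1 left 302 for NF-kB against GFP and 218 for NF-kB against STAT shRNAs. NF-kB hairpin 2 alone gave 320, and 154 genes were called with each hairpin.

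With the replicate number as a block, counts were 11 for 3'3'-cGAMP against c-di-AMP, 8 for 3'3'-cGAMP against c-di-GMP, 0 for STING against GFP shRNAs untreated and 736 for NF-kB against STAT shRNAs. Of pairs of libraries with the same number in different groups, 0 of 10 distinct values in polyps, 2 of 10 in the STING experiment and 1 of 14 in the NF-kB and STAT experiment were correlations above 0.1, so the numbers were not taken as pairs. Between 2 groups of 2 libraries the deviations mirror each other, so each such comparison holds 1 distinct value. In the STING experiment all 10 were above 0 (0.022 to 0.277). For the GFP shRNA response, the difference in response and STING against GFP shRNAs in 2'3'-cGAMP the number could not serve as a block, because the GFP shRNA 2'3'-cGAMP libraries carry other numbers than the rest. GFP shRNA 2'3'-cGAMP library 4 correlated with GFP shRNA untreated library 1 (0.352) and STING shRNA 1 untreated library 1 (0.354), the strongest values in that experiment. A block by the place in the sample order, which no label calls a batch, puts library 4 with the libraries numbered 1. It gave 1633 genes for the GFP shRNA response, 0 for the difference in response (limma, 433 at an unadjusted p below 0.05) and 0 for STING against GFP shRNAs in 2'3'-cGAMP (2934). For the difference in response of the polyp genes higher with 2'3'-cGAMP, camera's adjusted p was 0.043 over 4 tests with this block. The planned edgeR and DESeq2 tests on whole reads were not run, since whole reads were not recovered for part of the polyp values and nearly all embryo values.

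With 1 library left out, where a group of 2 leaves a lone library assumed to vary like the other groups, counts ran from 3 to 11 for 3'3'-cGAMP, 35 to 101 for c-di-AMP and 0 to 3 for c-di-GMP against untreated, 0 to 262 for 3'3'-cGAMP against c-di-AMP, 1 to 128 for 3'3'-cGAMP against c-di-GMP (highest without 3'3'-cGAMP library 1), and 51 to 123 for c-di-AMP against c-di-GMP. They ran from 735 to 2781 for the GFP shRNA response, 0 to 660 for the difference in response and 0 to 1506 for STING against GFP shRNAs untreated (highest without GFP shRNA untreated library 2), 1269 to 2300 for the STING shRNA response, and 0 to 70 for STING against GFP shRNAs in 2'3'-cGAMP (highest without GFP shRNA 2'3'-cGAMP library 5). For NF-kB against GFP shRNAs they ran from 188 to 761, for STAT against GFP from 1 to 18 and for NF-kB against STAT from 184 to 572.

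For the polyp genes higher and lower with 2'3'-cGAMP, camera's adjusted p with an estimated correlation was 0.385 and 0.246 for NF-kB and 0.138 and 0.0955 for STAT against GFP shRNAs. With the preset correlation, camera's adjusted p for the difference in response of the higher genes was 0.0198 with polyp genes of an absolute log2 change of at least 1, 0.0272 with a mean of at least 50 and 0.0428 with TMM factors (range over alternatives 0.0198 to 0.246, the latter with an estimated correlation), and for the lower genes 0.0402 with a mean of at least 50 (0.0402 to 0.181). With the preset correlation and 1 library left out it ran from 0.00606 to 0.614 for the higher and from 0.000757 to 0.745 for the lower genes, whose direction turned without GFP shRNA untreated library 1 (0.279) or 2'3'-cGAMP library 5 (0.745). For NF-kB against GFP shRNAs it ran from 0.000244 to 0.491 and from 2.92e-05 to 0.431.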

Other observations

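The tests of read depth and of distinct molecules behind the genes at 0, and of list means with equal library totals, were chosen after the result was seen, and the other tests here were chosen before. Both STING hairpins left a response to 2'3'-cGAMP. With STING shRNA 1, 867 genes were called higher and with STING shRNA 2, 692, of which 585 were shared (28.7 by chance). LOC5514999 rose by 5.20 on the log2 scale with STING shRNA 1 (adjusted p = 6.92e-05 by limma) and by 4.94 with STING shRNA 2 (0.00012), each against 6.03 with the GFP shRNA. Limma called 0 genes for the difference in response between the hairpins, with 309 at an unadjusted p below 0.05.

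With NF-kB and with STAT shRNAs the genes that c-di-AMP raised in polyps stood slightly lower. The list mean differed from that with the GFP shRNA by -0.33 on the log2 scale with NF-kB shRNAs (95% interval -0.58 to -0.08) and by -0.31 with STAT shRNAs (-0.56 to -0.06), and between NF-kB and STAT by -0.017 (-0.25 to 0.21). By hairpin the values were -0.495 (-0.792 to -0.198) with NF-kB shRNA 1 and -0.165 (-0.463 to 0.132) with NF-kB shRNA 2, with -0.33 (-0.655 to -0.004) between them, and -0.419 (-0.717 to -0.122) with STAT shRNA 1 and -0.206 (-0.503 to 0.091) with STAT shRNA 2, with -0.213 (-0.539 to 0.113) between them. With the preset correlation of 0.01, camera's adjusted p was 1.65e-09 for NF-kB and 1.35e-20 for STAT, but the correlation estimated between these genes was 0.236. With that estimate camera's adjusted p was 0.235 for NF-kB and 0.0837 for STAT. Fry's adjusted p was 0.0632 and 0.0688, all over 72 tests, so the lists passed only with the preset correlation. The interval for NF-kB included 0 without NF-kB shRNA 2 library 1 (-0.31), GFP shRNA library 2 (-0.30) or GFP shRNA library 3 (-0.30), and that for STAT without STAT shRNA 1 library 1 (-0.31), STAT shRNA 2 library 1 (-0.30), GFP shRNA library 2 (-0.28) or GFP shRNA library 3 (-0.29). The genes lower with NF-kB shRNAs rose by a mean of 3.00 on the log2 scale in 2'3'-cGAMP polyps (2.88 to 3.11), and those higher rose by 1.21 (1.12 to 1.31), with the deposited scaling. With equal library totals the means differed by 1.88 (1.66 to 2.10) and 0.074 (-0.09 to 0.24), so a rise of the latter list rests on that scaling.

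More than 50% of the tested polyp genes were called with 2'3'-cGAMP. The authors' scaling is argued against as the cause of the count, since the fewest genes called under equal totals, TMM factors or quantile scaling was 10193 of 18511, although it decides the balance of directions. Of 1995 genes with a mean of at least 1000, 82.5% were called, so calls were not confined to low values. This does not decide on lower read depth per gene, since that mean included the 2'3'-cGAMP libraries, through which raised genes could pass the limit. A few genes taking most of the counts is argued against. The 2'3'-cGAMP total still exceeded the untreated total 1.88 times without the 100 highest genes of each library (2.22 times with all genes). A broad change of the polyp transcriptome by this compound may account for the count, as a hypothesis found in the same data, and cell death or a change in cell types was not tested, since no marker could be named. A mixed or mislabelled sample was not tested either.

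Some embryo libraries had many more genes at 0 than others. In the STING experiment GFP shRNA untreated library 1, with 21.6% of genes at 0, had an estimated 18.6 M reads. There 2 libraries with fewer estimated reads had at most 7.6% of genes at 0. That depth is rough, since only 44.4% of the library's low values lay within 0.1 of a whole read, so depth stays open for it. Lower depth is argued against for GFP shRNA 2'3'-cGAMP library 4, with 14.4% of genes at 0 at an estimated 30.6 M reads. GFP shRNA untreated library 2 had 4.0% at 22.9 M, and in these 2 libraries 76.5% and 70.5% of low values lay that close. Fewer distinct molecules in the library may be the cause: among the 4 libraries of that experiment with most genes at 0 the ratio of genes at about 1 read to genes at 0 was at most 0.057, with a lowest value of 0.024, against 0.091 to 0.41 in its others. In the NF-kB and STAT experiment, NF-kB shRNA 2 library 1 had 14.0% of genes at 0 and a ratio of 0.048, but also the fewest estimated reads (14.4 M), so depth stays open there. Of its other libraries 3 had a ratio below 0.091 (0.056, 0.079 and 0.082). That ratio falls with the number of genes at 0 by its construction, so it does not decide the question, and no biological explanation was tested.

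Genes that responded together often lay side by side. Of the genes called higher with 2'3'-cGAMP in GFP shRNA embryos, 779 could be placed among 15782 genes in the order of the reference assembly, and they formed 132 adjacent pairs, against a median of 38 and a highest value of 65 in 10000 random relabellings (one-sided permutation p = 1e-04, the smallest they can give). Of the genes called lower with NF-kB shRNAs, 270 of 15346 formed 21 adjacent pairs, against a median of 5 and a highest value of 17 (one-sided permutation p = 1e-04, the smallest they can give). Clusters of related genes under shared control may explain this, but reads shared between similar neighbours would give the same pattern and were not tested.

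Libraries were split into groups of the same sizes in all 35 ways. The hairpins were pooled in these fits, so the counts differ from those above. For NF-kB against GFP shRNAs the real split called 430 genes and any other at most 107. For NF-kB against STAT shRNAs it called 357 against at most 1, and for the STING shRNA response 2777 against 0. In each of these the real split alone called as many genes. That share, 1 of 35, is the smallest the splits can give and was not adjusted over comparisons. The splits also take the libraries as independent, which the labels do not say. Chance is therefore made less likely there but not excluded. For STAT against GFP shRNAs the real split did not stand out, since 2 splits called at least its 1 gene. The other split, which set GFP shRNA library 1 with STAT shRNA 1 libraries 1 and 2 and STAT shRNA 2 library 1, called 35. That many calls under a wrong grouping points to a structure of these samples, whose source was not tested. This split put all 3 libraries numbered 1 on the same side, and with the replicate number as a block limma called 1 gene.

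The log2 changes of c-di-AMP and 2'3'-cGAMP against the same untreated libraries had a covariance of 0.452, against a mean of 0.13 over 20 draws of simulated groups without any change that shared those libraries. It was 0.253 against 0.131 for 3'3'-cGAMP and 2'3'-cGAMP, and 0.164 against 0.131 for 3'3'-cGAMP and c-di-AMP. The correlations were 0.401 (simulated 0.498), 0.259 (0.502) and 0.522 (0.502). For the pairs with 2'3'-cGAMP they cannot show or deny an excess, since the wide spread of its changes lowers a correlation in itself. No spread over the draws was taken for either measure. Measured against c-di-GMP, which left no library in common with 2'3'-cGAMP against untreated, the changes correlated with those of 2'3'-cGAMP at 0.17 for c-di-AMP and -0.0399 for 3'3'-cGAMP.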
